A study of Mus musculus with 24 samples.

How the data were processed

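The series measured gene expression by RNA sequencing in gastrocnemius muscle of C57BL/6 mice. Per the labels, the muscles were frozen, RNA was extracted with ISOGEN and RNeasy reagents, and a company made the libraries. The 24 libraries fall into 6 groups of 4. Wild-type (WT) mice carried floxed Notch2 alleles alone, and Notch2-mKO mice carried the same alleles with Cre recombinase expressed from the Mlc1f locus, which is active in skeletal muscle fibres. Each genotype was studied as a control, after 7 days of hindlimb suspension (unloading) and 14 days after a single injection of streptozotocin at 150 mg per kg, a toxin of pancreatic beta cells that produces insulin-deficient diabetes. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates came from separate animals, so the p-values measure the spread between these samples, part of which may be technical.

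The authors deposited 4 tables of 36172 gene models each, with RefSeq gene names per the file headers and the mouse build mm10 per the submitters' processing notes. The aligner and the counting tool are not given in the sources used here. Each table holds estimated counts per gene as deposited, which need not be whole, and log2 values made by the authors. Among the values above 0, 26.4 to 34.6% per library were whole within 0.001, and of the whole values up to 20 between 84.2 and 88.8% were even, the pattern left when each fragment is counted as 2 reads. The control libraries appear in 2 tables each, and all 8 control columns held identical values in both. The authors' log2 values, checked against the counts, use 1 scaling factor per library, a floor for low values, and subtraction of the mean of the 4 controls of the same genotype. They entered only an added alternative, since the counts keep the depth of each gene. No gene model of chromosome M is in the tables, so mitochondrially encoded genes were not analysed here. Of the 36172 models, 454 share a symbol with another and were kept apart.

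Totals per library ranged from 33112459 to 56369917 estimated counts, and 14226 to 14722 genes per library had a value above 0. At the depth of the shallowest library, 3 counts correspond to 0.0906 CPM (counts scaled to a common library total). The common biological coefficient of variation was 20.0%. Replicate libraries differed by far more than sampling noise (lowest chi-square per gene 14.6) and no pair looked like the same library deposited again, with Pearson correlations of log2 CPM between 0.969 and 0.987 across genes.

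Estimated counts were rounded to whole numbers and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. A single model with 1 coefficient per group was fitted to all 24 libraries, with TMM scaling factors and the default expression filter over the 6 groups, which kept 13048 genes. Contrasts compared each treatment with the controls of its genotype, Notch2-mKO with WT in each condition, and the 2 genotypes' responses to a treatment (interaction contrasts). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, and every adjusted p of a gene comes from this fit unless another tool is named. Fold changes carry standard errors (SE) from the fit, and group means are CPM ± SD over 4 libraries.

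Comparisons, tests, alternatives, the rule for naming genes and 34 gene lists were fixed before the data were examined. The lists cover wasting and protein breakdown, energy metabolism, fibre type, stress responses, matrix, Notch signalling and markers of other cell types of whole muscle. Of these, 31 had enough measured members, and 5 list genes were matched through older symbols. Each list was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry, which tests whether a list moves on balance in 1 direction without comparing it with other genes. With an estimated correlation no list passed in any of the 9 planned comparisons. Members were counted after adjustment over all genes and adjusted over the list alone. List p-values and member counts are given before removal of the GC and length trend described below, unless stated.

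Genes were named by this rule: Notch2 in every comparison; in each treatment comparison the 6 largest rises and 6 largest falls among called genes with a mean of at least 2 CPM and no overlap between the 4 treated and 4 control libraries; 4 and 4 by the same criteria in genotype comparisons and differences in response (without the overlap condition for the differences), where none qualified; the ubiquitin ligase genes Fbxo32, Trim63 and Fbxo30 in each treatment comparison whatever their p; and up to 4 members with the smallest p of a described list. Clone and model names and immunoglobulin or T cell receptor segments were passed over in the picks by size. Which lists are described, and which of their 4 leading members are named, was chosen after their values were seen. The same holds for members named because 5 or fewer of a list passed and for genes called by DESeq2 or a left-out library alone.

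The size of the response shared by both genotypes was scored per library as the mean log2 CPM of genes that rose minus that of genes that fell, for genes called on the response averaged over both genotypes. The treated-minus-control difference was compared between genotypes by an exact two-sided permutation of genotype labels within each condition (4900 arrangements). Overlaps of calls between treatments share the 4 control libraries of a genotype, so they are set beside 20 draws of simulated unchanged groups against those controls, the overlap of independent lists, and a repeat with the controls split 2 and 2.

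The alternatives set in advance were other scalings (DESeq2 size factors and upper quartile), DESeq2 1.42.0, no expression filter, only the compared groups in the fit, the replicate number as a block, a fold change limit, and each library left out in turn. Alternatives chosen after seeing the data were removal of each library's trend with GC content and gene length (natural splines with 4 and 2 knots as offsets in the same fit), halved counts, limma on the authors' log2 values, lists and counts without Notch2-mKO unloading replicate 1, treatments against the controls of the other genotype, and the 2 treatments compared directly. GC content and length came from the GENCODE annotation of mm10, in which 98.9% of tested genes had a match and 138 did not. Gene positions are 1-based mm10 coordinates from the same annotation.

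The fits were tested on simulated counts drawn from the real means and library sizes, with 200 of the tested genes changed. For WT unloading 81% of 2-fold and 100% of 4-fold changes were recovered and 4.74% of calls were false. For diabetes in Notch2-mKO the values were 83%, 100% and 3.68%, for the genotypes in control muscle 80%, 100% and 3.74%, and for the difference in unloading response 57%, 94% and 6.21%. When the libraries' GC and length trends were simulated for WT unloading without removing them, 1538 unchanged genes were called (89.5% of calls), against 11 with removal (5.73%). In the same way the false share was 18.9% for diabetes in Notch2-mKO and 9.5% with removal, 9.04% and 5.32% for the genotypes in control muscle, and 20.2% and 4.73% for the difference in unloading response. The simulated trend was the same spline fit that removal uses, so the lower false shares with removal follow largely from the construction. They do not show that removal works on the real trend. The simulation also counted the whole fitted trend as no change. Because of the false shares without removal, counts with the trend removed stand beside the others.

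Whether strand was used in counting is not given in the sources used here, so reads of overlapping genes cannot be told apart. Of 101 named genes, 28 share exon bases with another gene and 4 share at least 25% of theirs: Rsc1a1 lies wholly within exons of Ddi2, and Nrarp, Sox4 and Ctsl overlap predicted genes. Values of the near-identical pair Acot1 and Acot2 are likewise uncertain. Pseudocounts and filters planned for normalized values did not apply, since the tables hold counts. Results for a few genes are not reported here.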

Results

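Gene expression was measured in the gastrocnemius, the large muscle of the calf, in 4 libraries from each of 6 groups. WT mice and mice with Notch2 deleted in muscle fibres (Notch2-mKO) were studied as controls, after 7 days of hindlimb unloading and 14 days after streptozotocin. Notch2 encodes a receptor through which neighbouring cells signal to each other, and both treatments cause muscle wasting. The series title places the study as a test of whether loss of Notch2 alters wasting. Depth ranged from 33112459 to 56369917 estimated counts per library, and 13048 genes were tested.

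Libraries differed along a trend with base composition that ran alongside the treatments. The mean log2 level of 833 genes with under 42% GC minus that of 1488 genes with over 56% GC was -0.591 ± 0.316 (SD, n = 4) in WT controls, 0.392 ± 0.0623 in WT unloading and 0.320 ± 0.123 in WT diabetes. In Notch2-mKO muscle the values were -0.275 ± 0.237, 0.0407 ± 0.207 and 0.113 ± 0.132. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y, expressed in all libraries, were called higher in unloaded WT muscle, and 2 of these calls were left once each library's trend with GC content and length was removed. The authors' own log2 scaling shifted the median change of all genes upward by 0.251 and 0.263 for unloading and diabetes in WT and by 0.129 and 0.131 in Notch2-mKO. Changes are given relative to TMM scaling, and the other scalings moved that median by under 0.1.

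**Figure D1:**
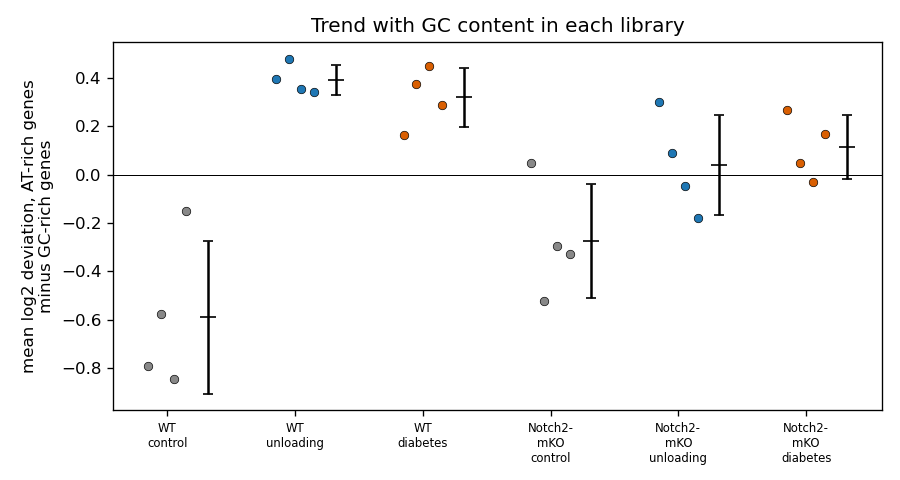
Mean log2 level of AT-rich genes minus that of GC-rich genes in each of the 24 libraries (points), by group, with the group mean and SD. The mean is lowest in WT controls (-0.591) and highest in WT unloading (0.392), and single libraries of different groups overlap.

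Notch2 (chromosome 3, 98013527 to 98150361, plus strand) was weakly expressed in whole muscle, with 51 to 166 counts per library. In WT libraries its level was 1.84 ± 0.068 CPM (SD, n = 4) in controls, 1.76 ± 0.31 after unloading and 2.28 ± 0.63 in diabetes. In libraries labelled Notch2-mKO it was 1.87 ± 0.58, 1.43 ± 0.12 and 1.78 ± 0.47 CPM. No difference in Notch2 between the genotypes passed the test in controls (log2 fold change 0.02, adjusted p = 0.993), unloading (-0.30, adjusted p = 0.696) or diabetes (-0.36, adjusted p = 0.878), nor did a change with treatment in either genotype (adjusted p between 0.332 and 0.902). The same held for the difference in its response between genotypes (adjusted p = 0.725 for unloading and 0.777 for diabetes). Counts cover the whole gene and every cell type of the muscle, whereas the deletion removes the floxed part in fibres alone, so the level of Notch2 does not check the genotype labels.

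In WT muscle, 7 days of unloading were followed by higher expression of protein breakdown genes and lower expression of collagen, tendon and mitochondrial genes. Trdn (chromosome 10, 33080554 to 33476709), which encodes triadin of the calcium release complex, rose from 74.5 ± 56.9 to 549 ± 116 CPM (SD, n = 4; log2 fold change 2.88, SE 0.386, adjusted p = 7.4e-06). Its call was kept with the trend removed, but its size there is not given here. Among WT controls Trdn was highest in replicate 4 (159 CPM, others 37.9 to 55.9). That library had an AT-rich minus GC-rich value of -0.150, others -0.578 to -0.846. Notch2-mKO control replicate 1 (248 CPM) lay above Notch2-mKO unloading replicate 4 (198.5). Igfn1 (chromosome 1, 135953578 to 136006342), a muscle gene of the immunoglobulin and fibronectin domain family, rose from 6.20 ± 2.57 to 45.5 ± 10.8 CPM. Actc1 (chromosome 2, 114047282 to 114053548), the cardiac actin gene, fell from 1168 ± 937 to 81.6 ± 84.0 CPM, and Col1a1 (chromosome 11, 94936224 to 94953042), the main chain of fibrillar collagen, fell from 225 ± 30.8 to 42.4 ± 33.8 CPM. The other largest rises were in Eda2r, a p53 target encoding a receptor (2.75), Tmem184c (2.55), the zinc finger gene Zfp51 (2.47) and Ift74 of ciliary transport (2.43, all log2). The other largest falls were in Rsc1a1 (-3.45), which lies inside exons of Ddi2, in Slc25a25 (-2.55), a mitochondrial ATP-Mg and phosphate carrier, in Chad (-2.50), a cartilage and tendon matrix gene, and in Rmi2 (-2.40). In other treated groups Rsc1a1 stayed high in single libraries. It was at 16.6 CPM in WT diabetes replicate 1 (others 0.304 to 0.663) and 12.4 in Notch2-mKO unloading replicate 1 (others 0.226 to 1.20). At an adjusted p below 0.05, 2395 genes were higher and 2127 lower (edgeR). With the GC and length trend removed the counts were 1815 and 1726, with limma on the authors' log2 values 3319 and 805. Of the 4522 genes called, 2455 were called with the trend removed too, 2424 of them with the same sign.

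Among the ubiquitin ligase genes, which mark proteins for degradation, Fbxo32 (chromosome 15, 58175879 to 58214932) rose from 112 ± 47.0 to 465 ± 397 CPM (log2 fold change 2.06, SE 0.564, adjusted p = 0.00634). Without WT unloading replicate 1 the change in Fbxo32 was 1.28 and not called (adjusted p = 0.0681). Trim63 (chromosome 4, 134315120 to 134329629) had 352 ± 230 CPM against 193 ± 25.5 and was not called (0.86, adjusted p = 0.129; 0.31 without WT unloading replicate 1, adjusted p = 0.621). Fbxo30 (chromosome 10, 11281330 to 11298052) rose by 1.20 (adjusted p = 0.00143), a call lost with the trend removed (0.40, adjusted p = 0.186). Of 21 atrophy genes 11 rose and none fell, 11 also when adjusted over the list alone, including Mstn (0.88), the growth inhibitor myostatin, and Nedd4 (0.44), another ubiquitin ligase. With the trend removed 5 of them were called and Mstn (0.09, adjusted p = 0.723) and Nedd4 (0.21, adjusted p = 0.0607) were not.

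Proteasome genes moved in 1 direction in unloaded WT muscle: 19 of 32 rose and 0 fell (21 adjusted over the list alone; camera adjusted p = 1.3e-05), among them the ATPase subunit Psmc6, from 25.3 ± 6.34 to 76.5 ± 22.7 CPM, and the activator Psme4 (0.88). With the trend removed the changes were 0.75 in Psmc6 and 0.48 in Psme4, both called. WT unloading replicate 1 stood apart for Psme4 (441 CPM, others 264 to 291), and without it 10 proteasome genes rose, 0 fell and the median log2 fold change of the list was 0.25, against 0.50 with it. Of 26 autophagy and lysosome genes 11 rose, among them Bnip3l (0.91; 0.40 with the trend removed), a receptor for removal of mitochondria, while the protease gene Atg4b fell (12 and 1 adjusted over the list alone; adjusted p = 0.0022). Extracellular matrix genes fell (24 of 30, 24 also adjusted over the list alone; adjusted p = 1.2e-09), with the collagen chaperone Serpinh1 at 23.8 ± 7.30 against 75.7 ± 7.20 CPM and the proteoglycan Bgn at -1.22, while the crosslinking enzyme gene Lox rose (1.02). Of 11 tendon genes 9 fell (9 adjusted over the list alone; adjusted p = 1.3e-05), including Thbs4 and Comp (-2.18). Of 50 nuclear-encoded oxidative phosphorylation genes 27 fell, including Atp5g1 of ATP synthase (-0.90), and Cox6c rose (0.59; 31 and 2 adjusted over the list alone; adjusted p = 2.5e-06). Chaperones fell in 12 of 20 cases, among them Cryab (-1.09), and rose in 2, Hspa4 and Hsp90aa1 (13 and 3 adjusted over the list alone; adjusted p = 0.0076). With an estimated correlation the adjusted p of these lists and of the atrophy genes lay between 0.39 and 0.546.

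Macrophage and endothelial markers fell too as lists in unloaded WT muscle, though not in every gene. The macrophage lysozyme gene Lyz2 lay higher, at 13.58 to 17.59 CPM against 9.138 to 12.96 in WT controls, and Cd163 overlapped with controls. Smooth muscle and pericyte genes were mixed. Rgs5 rose (1.22; 0.70 with the trend removed). Cspg4 lay lower (4.745 to 8.017 CPM, controls 9.11 to 11.94), as did Mcam (7.509 to 11.26, controls 13.77 to 17.82). Of 21 macrophage and leukocyte genes 12 fell (12 adjusted over the list alone; adjusted p = 6.7e-04), including Csf1r (-0.89) and C1qa (-0.93; -0.54 with the trend removed), and of 22 endothelial genes 8 fell (11 adjusted over the list alone; adjusted p = 0.0041), including Eng (-0.85) and Vwf (-1.03). Both had an adjusted p of 0.546 with an estimated correlation. Myh2, the myosin of fast oxidative fibres, fell from 2519 ± 341 to 806 ± 252 CPM, and the slow light chain Myl3 fell by 1.56 on the log2 scale. Among 25 Notch pathway genes Rbpj, Adam10 and Adam17 rose (3 adjusted over the list alone), falls included Notch3, Notch4 and Rfng, and the list was not called (adjusted p = 0.530).

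In Notch2-mKO muscle, unloading was followed by higher expression of proteasome genes and lower expression of tendon, collagen and mitochondrial genes. Igfn1 rose from 7.57 ± 2.55 to 50.5 ± 22.5 CPM (SD, n = 4; log2 fold change 2.74, SE 0.38, adjusted p = 3.77e-04), and Actc1 fell from 533 ± 368 to 70.3 ± 38.0 CPM. The other largest rises were in Tmem100, a membrane protein gene of the vasculature (2.28), Ppp1r15a, which restores translation after stress (1.93), Tmem184c (1.73), Ctxn3 (1.48) and the DNA repair gene Xpa (1.37). The other largest falls were in the mitochondrial carriers Slc25a25 (-2.91) and Slc25a30 (-2.44), in Ppp1r3c (-2.37), which directs a phosphatase to glycogen, and in the tendon genes Comp (-1.92) and Chad (-1.80). Calls that were lost when a single library was left out were Ctxn3 without unloading replicate 1 (adjusted p = 0.0622), Ppp1r15a without unloading replicate 4 (1.005, adjusted p = 0.0905) and Ppp1r3c without control replicate 3 (adjusted p = 0.0658).

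In all, 536 genes were higher and 418 lower in unloaded Notch2-mKO muscle (566 and 459 with the trend removed, which called 727 of the same genes, 435 and 547 with upper quartile scaling, 0 in all with limma on the authors' log2 values, 1455 in all with DESeq2). Without control replicates 2, 3 and 4 in turn the counts were 411, 504 and 439, and without unloading replicates 2 and 4 they were 610 and 570. The 3 ubiquitin ligase genes were not called: Fbxo32 had 475 ± 512 against 163 ± 37.5 CPM (1.54, adjusted p = 0.0832), Trim63 had a log2 fold change of 0.53 (adjusted p = 0.484) and Fbxo30 of 0.41 (adjusted p = 0.363). Without unloading replicate 4 the value for Fbxo32 was 0.44 (adjusted p = 0.635) and that for Trim63 turned to -0.38 (adjusted p = 0.577), while without unloading replicate 3 Fbxo32 was called (1.80, adjusted p = 0.0482). Fbxo30 was at 0.18 without control replicate 2, at 0.26 without unloading replicate 2 and at 0.19 with the trend removed. No difference from the WT response was called by edgeR, with values of -0.52 (adjusted p = 0.817) for Fbxo32, -0.34 (adjusted p = 0.853) for Trim63 and -0.80 (adjusted p = 0.345) for Fbxo30. The sign for Fbxo32 and Trim63 rests on single libraries: without WT unloading replicate 1 their differences were 0.26 and 0.22, and without Notch2-mKO unloading replicate 4 they were -1.60 and -1.23. Removing the trend gave -0.34 for Fbxo32 and -0.21 for Fbxo30.

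Proteasome genes rose in unloaded Notch2-mKO muscle as well: 13 of 32 were called (22 adjusted over the list alone; camera adjusted p = 7.9e-11), among them Psma7 (0.90) and Psmc6 (0.87; 0.56 with the trend removed), and 0 fell. Without control replicates 1, 2, 3 and 4 in turn 7, 6, 8 and 3 proteasome genes were called, and 6 without unloading replicate 1 or 4. Oxidative phosphorylation genes fell (9 of 50, 25 adjusted over the list alone; adjusted p = 3.7e-12), including Atp5g3 (-0.73) and Sdhb (-0.66). Tendon genes (8 of 11 fell; 9 fell and 1 rose adjusted over the list alone; adjusted p = 3.1e-08) and extracellular matrix genes (11 of 30 fell; 19 adjusted over the list alone; adjusted p = 1.6e-07) included Thbs4 (-1.14) and Serpinh1 (-0.91). Endothelial genes fell (6 of 22, 10 adjusted over the list alone; adjusted p = 1.6e-05), among them Eng (-0.64) and Vwf (-0.70), and 6 of 20 chaperones did (6 adjusted over the list alone; adjusted p = 4.6e-04), among them Hsph1 (-0.92). Bnip3l (0.60; 0.40 with the trend removed), Bnip3, Map1lc3a and Lamp2 rose among the 26 autophagy and lysosome genes (4 adjusted over the list alone; adjusted p = 0.0012), though Lamp2 lost its call in 6 of 8 fits with a library left out (adjusted p 0.0635 to 0.0983) and with the trend removed (adjusted p = 0.278). These 7 lists had adjusted p between 0.356 and 0.392 with an estimated correlation. No macrophage gene was called by edgeR with all libraries and no replicate block (list adjusted p = 0.798). Lyz2, the macrophage lysozyme gene, came closest (0.68, adjusted p = 0.0546), and was called by DESeq2 (adjusted p = 0.0269) and without control replicates 1 or 4 or unloading replicate 2 (adjusted p 0.0307 to 0.0444). Notch1 (-0.92) and Notch4 (-0.97) fell among the 25 Notch pathway genes (3 adjusted over the list alone; adjusted p = 0.0466, and 0.468 with an estimated correlation).

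**Figure D2:**
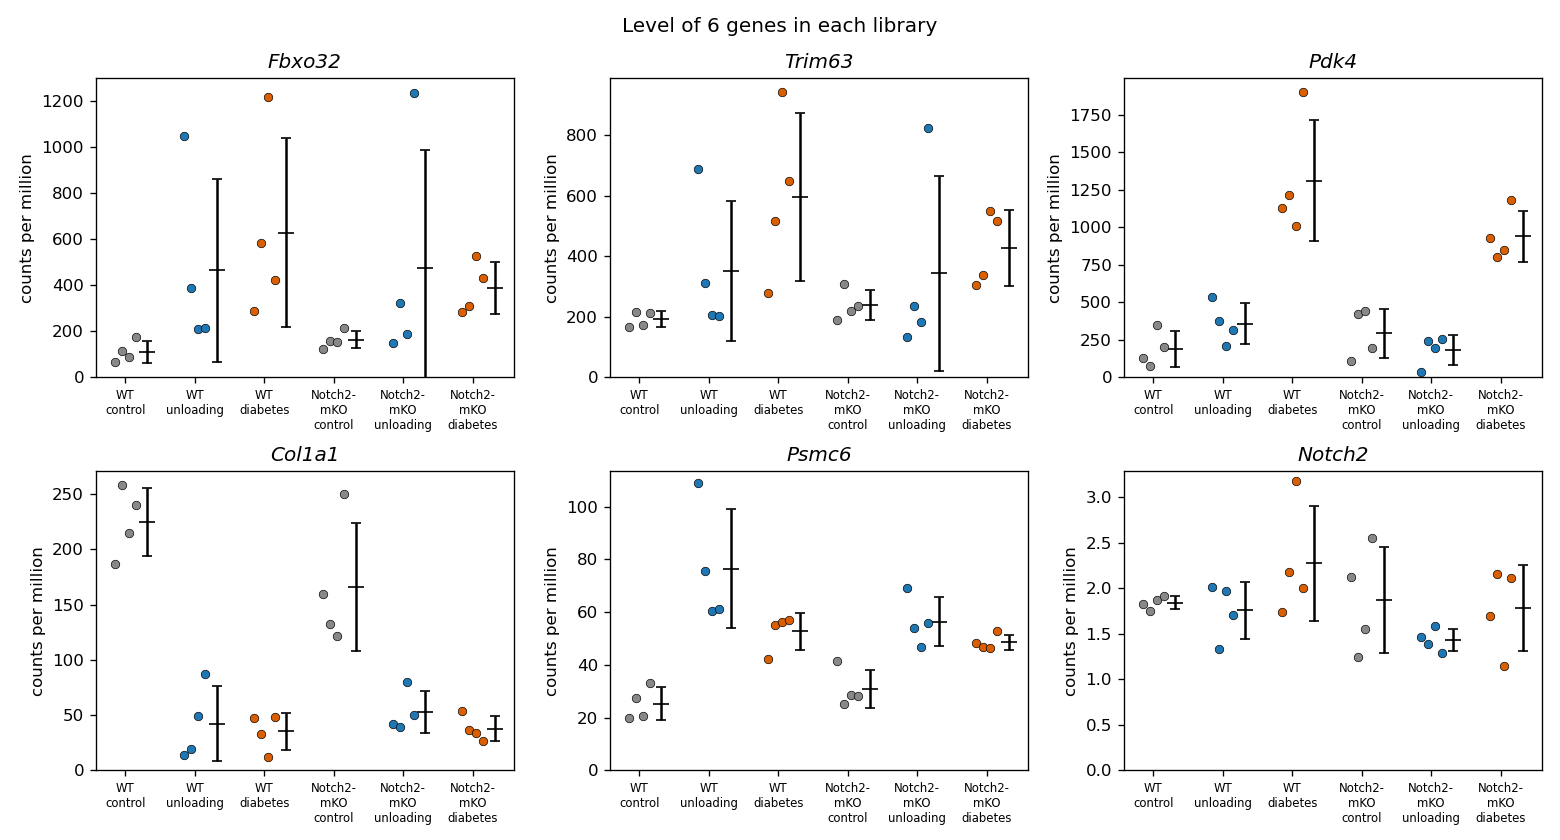
CPM of Fbxo32, Trim63, Pdk4, Col1a1, Psmc6 and Notch2 in each library (points) of the 6 groups, with the mean (tick) and SD (bar, ending at 0 where mean minus SD lies below it). Col1a1 lies near 225 CPM in WT controls and near 42.4 after unloading, and the Notch2 levels of the genotypes overlap in every condition.

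In diabetic WT muscle, genes of fatty acid use rose and genes of oxidative phosphorylation, collagen, tendon and glucose uptake fell. Acot1 (chromosome 12, 84009490 to 84018371), a cytosolic thioesterase gene induced by fatty acids, rose from 0.951 ± 0.255 to 16.5 ± 4.98 CPM (SD, n = 4; log2 fold change 4.13, SE 0.502, adjusted p = 5.89e-06), and its near-copy Acot2 by 3.26. Pdk4 (chromosome 6, 5483351 to 5496309), which inhibits the conversion of pyruvate to acetyl-CoA, rose from 191 ± 120 to 1312 ± 401 CPM. The other largest rises were in the transcription factor gene Sox4 (3.14), Trdn (2.83) and the nuclear receptor gene Nr4a3 (2.79). The largest falls were in Scd1 (-2.81), the desaturase of lipid synthesis, Gamt (-2.73), which completes creatine synthesis, Col1a1, at 35.5 ± 16.7 CPM (-2.67), Chad (-2.64), Cilp2 (-2.61) and Col5a3 (-2.60), the last 4 all genes of matrix or cartilage. In all, 2327 genes were higher and 2027 lower (1669 and 1622 with the trend removed, 2994 and 602 with limma on the authors' log2 values). Of the 4354 genes called, 2343 were called with the trend removed too, 2320 of them with the same sign.

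Fbxo32 rose from 112 ± 47.0 to 628 ± 410 CPM (2.49, SE 0.573, adjusted p = 0.00174) and Trim63 from 193 ± 25.5 to 596 ± 276 CPM (1.63, adjusted p = 0.00668) in diabetic WT muscle. Fbxo30 was called at 0.75 (adjusted p = 0.0367), but not in 6 of 8 fits with a library left out (adjusted p 0.0530 to 0.125) and with a change of -0.01 once the trend was removed (adjusted p = 0.978). Of 21 atrophy genes 13 rose (13 adjusted over the list alone; camera adjusted p = 7.1e-04), including the lysosomal protease Ctsl (0.92) and Nedd4 (0.54), at 0.53 and 0.29 with the trend removed. Of 20 glucocorticoid and FOXO responsive genes 12 rose (12 adjusted over the list alone; adjusted p = 7.1e-04), among them the transcription factor gene Klf9 (1.20). Fatty acid oxidation genes rose in 20 of 29 cases (21 adjusted over the list alone; adjusted p = 1.2e-08), including Acadl (1.51) and Ech1 (0.78) of beta-oxidation, and Plin2, which coats lipid droplets, fell (-0.54). Oxidative phosphorylation genes fell (33 of 50, 37 adjusted over the list alone; adjusted p = 1.7e-11), including Cox5b of cytochrome c oxidase (-1.08). Extracellular matrix genes fell in 22 of 30 cases while Lox rose (22 and 1 adjusted over the list alone; adjusted p = 2.4e-08), and 8 of 11 tendon genes fell (8 adjusted over the list alone; adjusted p = 9.6e-06), with Serpinh1 at -1.47 and Tnmd at -2.55. Of the glucose uptake and glycolysis genes 10 fell, among them the insulin-responsive transporter Slc2a4, from 677 ± 90.7 to 337 ± 107 CPM, and Hk1 (-0.77), while Ppp1r3a and Gyg rose (13 and 2 adjusted over the list alone; adjusted p = 0.0218). With an estimated correlation the adjusted p of these lists lay between 0.432 and 0.703. The list p-values are from values before removal of the GC and length trend. Genes called lower had a median GC content of 54.17% and a median length of 2734 bases, against 43.89% and 4328 in genes called higher. How much of each list's change follows the trend is not given here.

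Proteasome genes were not called as a list in diabetic WT muscle (adjusted p = 0.842). Psmc6, Psmd11 and Psme4 rose and Psmb5 and Psmb6 fell (2 and 0 adjusted over the list alone), and Psmc6 was not called with the trend removed (0.31, adjusted p = 0.0963). Of 25 Notch pathway genes Rbpj, Adam10, Adam17, Jag1 and Hey2 rose and Nrarp (-1.36), Rfng (-0.64) and Hes1 fell (5 and 3 adjusted over the list alone; adjusted p = 0.928). Hey2 was barely counted, at 0 to 0.0619 CPM in WT controls and 0.128 to 0.278 in WT diabetes. Nrarp shares most of its exon bases with a predicted antisense gene, and Rfng lost its call with the trend removed (-0.32, adjusted p = 0.0995).

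In diabetic Notch2-mKO muscle, genes of fatty acid use rose and genes of collagen, tendon and oxidative phosphorylation fell. Acot1 rose from 1.07 ± 0.510 to 12.3 ± 3.67 CPM (SD, n = 4; log2 fold change 3.51, SE 0.483, adjusted p = 4.3e-04) and Acot2 by 2.13. Chrna2, a subunit of the neuronal acetylcholine receptor, rose by 2.60 and the interferon-induced GTPase gene Tgtp1 by 2.04. Col1a1 fell from 166 ± 58.2 to 37.7 ± 11.4 CPM, and Cilp2 (-2.51) and Col5a3 (-2.35) fell with it. The remaining picks by size were Sox4 (2.43), the secreted glycoprotein gene Stc2 (2.11), Rsc1a1 (-4.51), the endothelial protocadherin gene Pcdh12 (-2.22) and Scd1 (-2.14). Each of these lost its call without diabetes replicate 4 (adjusted p = 0.0666 for Sox4, 0.0641 for Stc2, 0.054 for Pcdh12, 0.0545 for Rsc1a1 and 0.0792 for Scd1). Without control replicate 4 the calls of Stc2 (adjusted p = 0.0532), Pcdh12 (0.0759) and Scd1 (0.0516) were lost, without diabetes replicate 2 those of Rsc1a1 (0.0507) and Scd1 (0.0573), and without diabetes replicate 3 that of Scd1 (0.0682).

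In all, 398 genes were higher and 332 lower (297 and 289 with the trend removed, which called 447 of the same genes, 1425 and 351 with limma on the authors' log2 values, 1592 in all when only the compared groups were fitted and 1142 with DESeq2). Left-out libraries lowered the count of 730 in diabetic Notch2-mKO muscle to 275, 320 and 153 without control replicates 2, 3 and 4, and to 346, 257, 310 and 178 without diabetes replicates 1, 2, 3 and 4. Fbxo32, at 389 ± 113 against 163 ± 37.5 CPM (1.25, adjusted p = 0.175), Trim63 (0.84, adjusted p = 0.262) and Fbxo30 (0.40, adjusted p = 0.406, from 0.18 to 0.62 with a library left out and 0.08 with the trend removed) were not called. The differences from the WT response, -1.24 (adjusted p = 0.664), -0.78 (adjusted p = 0.743) and -0.35 (adjusted p = 0.831), were not called by edgeR. Without WT diabetes replicate 3 the difference was -0.70 for Fbxo32 and -0.47 for Trim63, and that for Fbxo30 ranged from -0.57 without Notch2-mKO control replicate 2 to -0.13 without Notch2-mKO control replicate 1 and was 0.09 with the trend removed.

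Fatty acid oxidation genes rose in diabetic Notch2-mKO muscle (12 of 29, 20 adjusted over the list alone; camera adjusted p = 6.6e-14), including Ech1 (0.74) and the fatty acid binding protein Fabp3, from 324 ± 33.3 to 689 ± 119 CPM. Oxidative phosphorylation genes fell (12 of 50, 28 adjusted over the list alone; adjusted p = 2.8e-15), including Cox8b (-0.67; -0.43 with the trend removed) and Cox5b (-0.70). Extracellular matrix genes (17 of 30; 20 fell and 1 rose adjusted over the list alone) and tendon genes (9 of 11; 9 adjusted over the list alone) fell, each with an adjusted p of 1.8e-10, among them Col1a2 (-1.84), Thbs4 (-1.25) and Chad (-2.12). Klf9, Cebpd, Cebpb and Pdk4 rose among the 20 glucocorticoid and FOXO responsive genes (4 adjusted over the list alone; adjusted p = 5.9e-06). These 4 calls were lost in several fits with a library left out, Cebpb in 2 of 8 (adjusted p 0.0707 to 0.0726), Klf9 in 5 (0.0525 to 0.0852), Cebpd in 6 (0.0543 to 0.114) and Pdk4 in 7 (0.0542 to 0.126). Pdk4 was not called with the trend removed either (1.54, adjusted p = 0.0683). None of the 21 atrophy genes was called over all genes by edgeR, while Gadd45a, Ctsl, Nedd4 and Cblb passed when adjusted over the list alone (4 genes) and the list was called (adjusted p = 2.7e-04). Over all genes DESeq2 called Gadd45a (adjusted p = 0.0436) and Ctsl (adjusted p = 0.0284), and edgeR called Gadd45a with the trend removed (adjusted p = 0.0439) and Ctsl without control replicate 1 (0.65, adjusted p = 0.0430). These 6 lists had adjusted p between 0.163 and 0.381 with an estimated correlation. Nrarp (-1.38) was the 1 Notch pathway gene that fell (1 adjusted over the list alone; list adjusted p = 0.142), a call lost in 5 of 8 fits with a library left out (adjusted p 0.0511 to 0.207), with a change of -0.63 without control replicate 4.

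**Figure D3:**
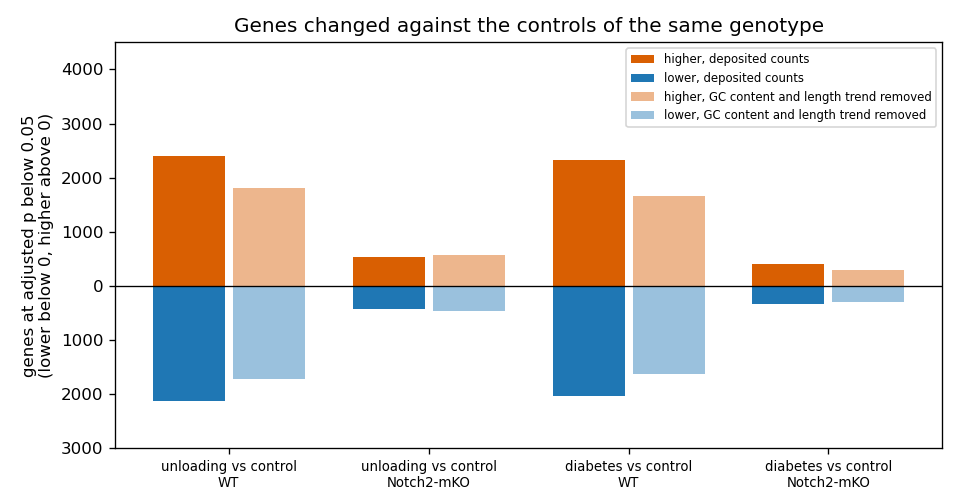
Number of genes called higher (above 0) and lower (below 0) in each treatment comparison, from the deposited counts and with each library's GC and length trend removed. Unloading and diabetes in WT give the most calls, 4522 and 4354 before removal, against 3541 and 3291 with the trend removed.

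**Figure D4:**
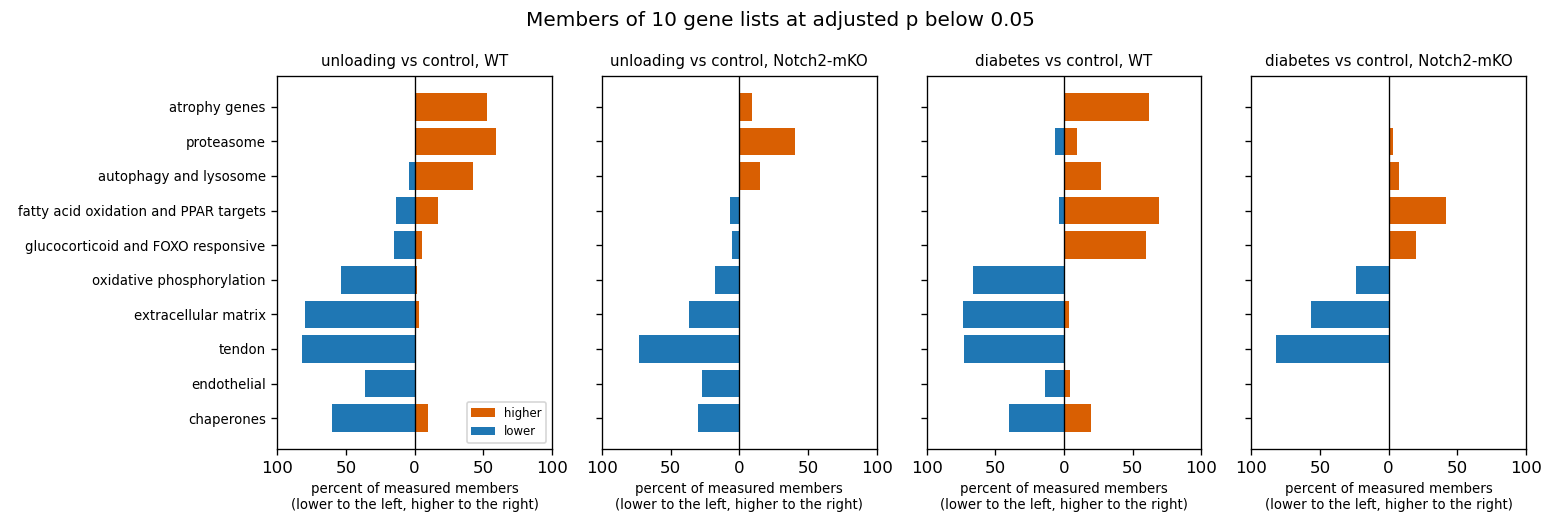
Percent of measured members called higher (to the right) and lower (to the left) in 10 gene lists for each treatment comparison. Proteasome genes were called higher after unloading, 19 of 32 in WT and 13 in Notch2-mKO, and fatty acid oxidation genes in diabetes, 20 of 29 and 12.

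The direct comparison of genotypes asks whether Notch2 deletion changed muscle expression within a condition. By edgeR 0 genes were called between Notch2-mKO and WT in controls, unloading or diabetes, with 695, 1345 and 692 genes at an unadjusted p below 0.05 where 652 would be expected by chance. With the trend removed 476, 944 and 634 genes had such a p and 0 were called. The smallest adjusted p before removal was 0.0841, 0.305 and 0.872. DESeq2 called Lancl1, Ear2 and Mtm1 in controls, Lrfn3, Dek, Tkt, Dap and Ddx3y in unloading, and 0 in diabetes. Upper quartile scaling called Lancl1 in controls, and fits of the compared groups alone called Wdfy1 in controls and Dek in unloading. With a library left out, edgeR called Lancl1 and Rsrc2 in controls without WT control replicate 4, Tkt in unloading without Notch2-mKO unloading replicate 2, and the clone-named transcript A230073K19Rik in diabetes without WT diabetes replicate 1.

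As groups, extracellular matrix genes (median log2 fold change -0.29, camera adjusted p = 2.4e-06) and macrophage genes (-0.22, adjusted p = 4.6e-06) were lower in Notch2-mKO than in WT controls, and fatty acid oxidation genes were higher (0.16, adjusted p = 0.0075). In unloading, macrophage genes were higher in Notch2-mKO (0.37, adjusted p = 1.4e-04; 7 of 21 adjusted over the list alone), led by Fcer1g (0.75) and C1qa (0.63, adjusted p = 0.388 each), and so were matrix genes (0.19, adjusted p = 0.0167). In diabetes, oxidative phosphorylation genes (0.16, adjusted p = 9.1e-08) and adipocyte genes (0.58, adjusted p = 0.0076) were higher in Notch2-mKO, the latter led by Adipoq (1.12, adjusted p = 0.872; 1.77 without WT diabetes replicate 4, adjusted p = 0.437). No member of these lists was called over all genes by edgeR. With an estimated correlation the adjusted p was 0.926 in controls, 0.958 in unloading and 0.971 in diabetes, and fry called none of these lists. These list values are those before removal of the GC and length trend, and values after removal are not given here. Fold changes between genotypes correlated with GC content across genes (Spearman rho -0.566 in controls, 0.491 in unloading and 0.347 in diabetes).

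The genotypes' responses were compared gene by gene with interaction contrasts. By edgeR 0 genes responded differently to unloading (1875 at an unadjusted p below 0.05, smallest adjusted p 0.0943) or diabetes (1142, smallest adjusted p 0.414). With the trend removed the counts at an unadjusted p below 0.05 were 1168 and 713, where 652 would be expected by chance, and 0 genes were called. DESeq2 called 22 genes higher and 101 lower for unloading, and Ckap5, Zfp287 and Mtm1 for diabetes. The count by edgeR rose to 427 for unloading and 62 for diabetes without WT control replicate 4, and for unloading to 12 without WT unloading replicate 4, to 1 (Mtm1) without Notch2-mKO control replicate 4 and to 1 (Tkt) without Notch2-mKO unloading replicate 2. As a list, macrophage genes responded to unloading less negatively in Notch2-mKO (median difference 0.73, camera adjusted p = 3.2e-07; 8 of 21 adjusted over the list alone; adjusted p = 0.665 with an estimated correlation), with C1qa differing by 0.89 (adjusted p = 0.152; 0.59 with the trend removed) and H2-Ab1 by 1.04 (adjusted p = 0.172). So did matrix genes (0.54, adjusted p = 1.1e-05; 1 of 30 adjusted over the list alone; adjusted p = 0.979 with an estimated correlation), with Bgn differing by 0.94 (adjusted p = 0.122), called by DESeq2 (0.93, adjusted p = 0.0255) and by edgeR without WT control replicate 4 (0.97, adjusted p = 0.0251) or WT unloading replicate 4 (1.08, adjusted p = 0.0422). For diabetes, matrix genes differed by 0.31 and oxidative phosphorylation genes by 0.14 (adjusted p = 0.0167 each, 0.89 with an estimated correlation). These list values are those before removal of the trend, and values after removal are not given here. Differences in response correlated with GC content across genes (Spearman rho 0.593 for unloading and 0.551 for diabetes).

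Over the genes that changed on average across both genotypes, the response to each treatment was smaller in libraries labelled Notch2-mKO than in WT. For unloading, the score over 2757 genes that rose and 2386 that fell moved from -0.821 ± 0.251 (SD, n = 4) to 0.683 ± 0.221 in WT and from -0.529 ± 0.181 to 0.364 ± 0.151 in Notch2-mKO. The change of 0.893 in Notch2-mKO was 0.594 times that of 1.504 in WT (two-sided exact permutation p = 0.0102). For diabetes, with 2602 genes that rose and 2410 that fell, the score moved from -1.09 ± 0.250 to 0.463 ± 0.349 in WT and from -0.769 ± 0.206 to 0.177 ± 0.0577 in Notch2-mKO, a ratio of 0.607 (two-sided exact permutation p = 0.0184; 0.0502 without Notch2-mKO control replicate 1). With the trend removed the ratios were 0.677 (exact p = 0.0261) and 0.669 (exact p = 0.0294). No difference passed in the treated or the control libraries alone: treated WT exceeded treated Notch2-mKO by 0.319 for unloading (exact permutation p = 0.0571) and 0.286 for diabetes (exact p = 0.171), and WT controls lay lower by 0.292 (exact p = 0.143) and 0.325 (exact p = 0.114). The same control libraries enter both treatments, so the 2 results are not independent.

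**Figure D5:**
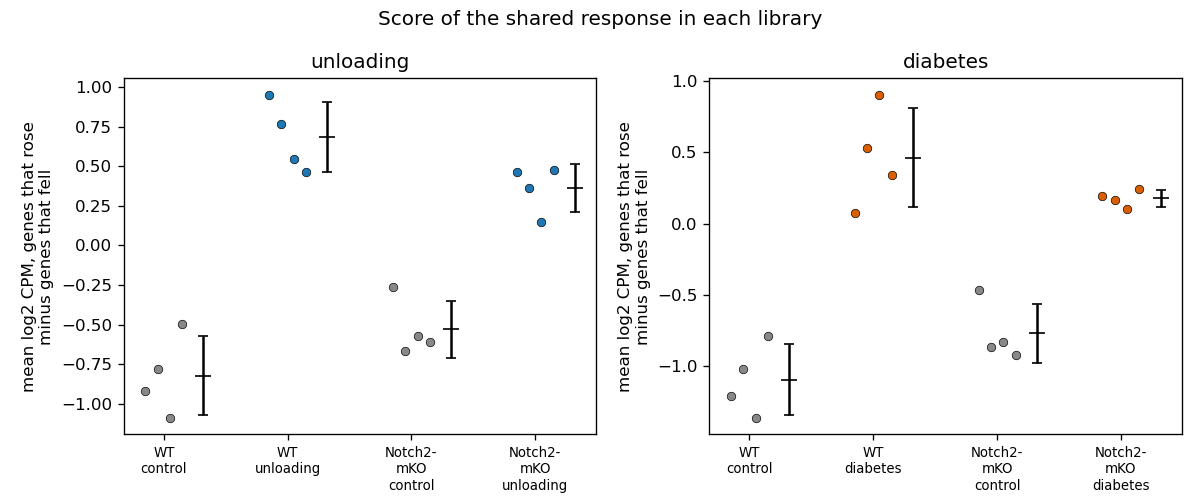
Score of the shared response in each library (points) for unloading and diabetes, in mean log2 CPM of genes that rose minus genes that fell, with group means and SD. The step from control to treated is 1.504 in WT and 0.893 in Notch2-mKO for unloading, and 1.56 and 0.945 for diabetes.

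Unloading and diabetes were compared for overlap within each genotype. In WT, 1760 genes were higher and 1316 lower in both treatments, where independent lists would share 427 and 330, and 8 changed in opposite directions. In Notch2-mKO, 143 were higher and 106 lower in both against 16.4 and 10.6 for independent lists, and 5 were opposite. Trdn was higher and Col1a1 lower in both treatments in WT, and Comp and Thbs4 were lower in both treatments in both genotypes. Unchanged groups simulated against the same controls shared 0 genes. The simulation held none of the libraries' GC and length trend, so it cannot tell how much of the overlap follows that trend. Fold changes correlated with GC content across genes for unloading and diabetes (Spearman rho -0.54 and -0.52 in WT, -0.28 and -0.36 in Notch2-mKO). Across genes, which are not independent replicates, fold changes correlated at 0.780 in WT and 0.573 in Notch2-mKO, against 0.525 and 0.501 in the simulation. The covariance was 0.370 in WT against 0.0542 simulated, and 0.132 against 0.0499 in Notch2-mKO. With the controls split 2 and 2 between the treatments the mean overlap was 1622 genes in WT and 16.3 in Notch2-mKO. Each comparison then rests on 2 controls, which by itself can lower the number of calls. The fall therefore does not measure how much of the overlap comes from shared controls. The overlap of 249 genes in Notch2-mKO was 396 without control replicate 1, 74, 99 and 46 without control replicates 2, 3 and 4, 160 without unloading replicate 2, and 135, 105, 109 and 60 without diabetes replicates 1 to 4.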

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

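For the smaller response in Notch2-mKO, the tests of the GC and length trend, of the WT control libraries and of loss of Notch2 were chosen after the result was seen, and the criterion for the WT control libraries was reworded after its values had been seen.

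The step of the shared response score from control to treated in Notch2-mKO was 0.594 times that in WT for unloading and 0.607 times for diabetes, singled out by the exact test of the difference between genotypes. The tables argue against the GC and length trend as the whole cause, since the difference kept an exact permutation p of 0.0261 and 0.0294 with the trend removed. An unusual set of WT control libraries, which enter both treatments, stays open: the treated libraries alone differed between genotypes with an exact permutation p of 0.0571 and 0.171, which does not decide it. Loss of Notch2 stays open too: its exact permutation p (0.0102 and 0.0184) is that of the difference itself and tests no cause, the level of Notch2 does not check the genotype labels, and no other cohort was analysed here. A smaller response with loss of Notch2 is therefore a hypothesis, found and tested on the same libraries.

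In Notch2-mKO unloading replicate 1 the 10 most abundant genes held 27.8% of counts, the lowest of all libraries, against 35.9 to 36.7% in the others of its group. A control library under a wrong label is argued against by its score of the unloading response, which lay 2.54 SDs above the highest Notch2-mKO control. A large excess of the cell types covered by 9 marker lists is argued against. The largest excess over the rest of the group, in macrophage genes, was 0.116 on the log2 scale. Cells or tissue outside these lists were not tested. No biological explanation was tested, and the count of calls without this library is among the alternatives.

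Single libraries stood apart in 34 of 429 groups of 4 libraries examined for named genes and library measures, by a gap to the next library that took up most of the group's range (Dixon's test). For normally distributed and independent values chance gives about 1 in 20, or 21. CPM were used untransformed and several genes flag the same library, so 34 against 21 does not test chance. The libraries that stood apart for named genes are listed by group. In WT controls these were Acot1 in replicate 2 (0.570 CPM, others 1.05 to 1.10), C1qa (18.8, others 14.1 to 14.7), Hk1 (14.3, others 11.01 to 11.5) and Myh3 (1.29, others 2.85 to 3.06) in replicate 1, Fads2 (1.90, others 3.11 to 3.28), Ift74 (0.255, others 1.02 to 1.14), Ndufb10 (443, others 321 to 335) and Thbs4 (112, others 76.5 to 82.4) in replicate 3, and Trdn in replicate 4 (159, others 37.9 to 55.9). In Notch2-mKO controls they were Acot2 (3.15 CPM, others 2.21 to 2.30), Cilp2 (5.81, others 10.6 to 11.04), Cox5b (568, others 481 to 493) and Hsph1 (120.1, others 70.0 to 75.0) in replicate 3 and Actc1 in replicate 4 (1081, others 288 to 410).

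After unloading, WT replicate 1 stood apart for the proteasome genes Psmb2 (104 CPM, others 58.3 to 62.7), Psmc3 (430.2, others 282 to 296) and Psme4 (441, others 264 to 291), for Mllt11 (317, others 135 to 154) and for Nr4a3 (2.42, others 0.271 to 0.419). WT unloading replicate 2 stood apart for Nfil3 (10.9 CPM, others 8.4 to 8.71), Notch4 (7.19, others 5.05 to 5.28) and Ppp1r3c (143, others 67.3 to 76.9), and replicate 3 for Chad (6.15, others 3.67 to 3.96). Notch2-mKO unloading replicate 4 stood apart for Fbxo32 (1234 CPM, others 150.5 to 325), Trim63 (822, others 133 to 235), Ppp1r15a (111, others 18.5 to 29.2) and Psmc3 (431, others 300.1 to 320).

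In diabetes, WT replicate 1 stood apart for Psmc6 (42.3 CPM, others 55.3 to 57.1), replicate 3 for Cebpd (172, others 49.6 to 68.7) and Myh3 (19.6, others 5.10 to 5.56) and replicate 4 for Adipoq (6.82, others 1.74 to 2.33). Notch2-mKO diabetes replicate 4 stood apart for Ech1 (269 CPM, others 301 to 305) and Serpinh1 (23.4, others 32.4 to 34.1).

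The test of the difference in response between genotypes also singled out whole lists, given as median difference in log2 fold change, Notch2-mKO minus WT. For unloading these were extracellular matrix (0.54), fatty acid oxidation (-0.13), macrophage (0.73) and Y-linked genes (-0.70), and for diabetes extracellular matrix (0.31), oxidative phosphorylation (0.14) and Y-linked genes (-0.74). None of these list differences passed with an estimated correlation. They are given before removal of the GC and length trend, and their values after removal are not given here.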

How the results depend on the processing

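Fits with the GC and length trend removed, with halved counts, with limma on the authors' log2 values, without Notch2-mKO unloading replicate 1, against the controls of the other genotype and of the 2 treatments directly were chosen after seeing the data. Of 233 values of named genes, 232 kept their status as called or not called with DESeq2 size factors, 228 with the DESeq2 test and 220 with the trend removed. Many of these genes were picked for size or a small p, so the shares do not hold for all genes. Of the 4522 genes called for unloading in WT, 2455 were called with the trend removed too. The 1 called value whose sign turned was Fbxo30 in diabetic WT muscle with the trend removed (-0.0105). In the order unloading WT, unloading Notch2-mKO, diabetes WT and diabetes Notch2-mKO, the counts of 4522, 954, 4354 and 730 stayed within 1.5 times with DESeq2 size factors, upper quartile scaling, no expression filter, halved counts and the trend removed. The cause was not tested for the changes below except where the setting gives it. Pseudocounts and low-value filters for normalized values were not run, because the tables hold counts.

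A log2 fold change of at least 1 in either direction, which by construction keeps fewer genes, left 1155, 163, 1155 and 202 genes, and 155 in WT and 154 in Notch2-mKO between diabetes and unloading. DESeq2 called 1455 for unloading and 1142 for diabetes in Notch2-mKO, 3 and 5 between genotypes in controls and unloading, 123 and 3 for the differences in response, 697 between the treatments in WT, and 450 genes shared by both treatments in Notch2-mKO. Fitting only the compared groups gave 331 for unloading and 1592 for diabetes in Notch2-mKO, 1 each between genotypes in controls and unloading, and 257 between the treatments in WT (194 higher, 63 lower). With limma on the authors' log2 values unloading in Notch2-mKO gave 0 and diabetes 1776, and upper quartile scaling gave 1 between genotypes in controls. With the controls split 2 and 2, which leaves 2 controls in each comparison, the overlap of treatments was 1622 genes in WT and 16.3 in Notch2-mKO.

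Gene lists called at the preset correlation numbered 11, 17, 11 and 10 for the treatments, 4, 3 and 2 between genotypes, 4 and 3 for the differences in response, and 10 and 8 between the treatments. With an estimated correlation these became 0 in the first 9 and 1 in each genotype between the treatments. Fry gave 17 for unloading in WT, 9 in Notch2-mKO, 0 between genotypes and for the differences, and 4 and 3 between the treatments. With the trend removed 9 lists were called for unloading in Notch2-mKO and 7 for diabetes in WT. Which lists these are is not given here. Without Notch2-mKO unloading replicate 1, 12 lists were called for unloading in Notch2-mKO, 6 between genotypes in unloading, 5 for the difference in unloading response and 12 between the treatments in Notch2-mKO, and 672 genes for unloading.

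With each library left out in turn, the lowest and highest counts were 3667 and 4742 for unloading in WT, 411 and 1127 in Notch2-mKO, 3340 and 4479 for diabetes in WT and 153 and 995 in Notch2-mKO. Between genotypes they were 0 and 2 in controls, 0 and 1 in unloading, and 0 and 1 in diabetes, and for the differences 0 and 427 for unloading and 0 and 62 for diabetes. Between the treatments they were 278 and 468 in WT and 195 and 342 in Notch2-mKO, and for the overlap of treatments 2314 and 3351 in WT and 46 and 396 in Notch2-mKO. The ratio of shared responses ranged from 0.534 to 0.664 for unloading and from 0.550 to 0.682 for diabetes. Of 1936 values of named genes, 1766 kept their status as called or not called, 162 lost a call and 8 gained one. Without Notch2-mKO control replicate 2 or 4, calls for unloading split 189 higher to 222 lower and 197 to 242, and without control replicate 2 those for diabetes split 121 to 154, against 536 to 418 and 398 to 332 with all libraries.

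The replicate number as a block gave 4371, 729, 4196 and 488 genes for the treatments, 0 between genotypes and for the differences, and 422 and 343 between the treatments. With it 225 of the 233 named values kept their status as called or not called, and Lyz2 in unloaded Notch2-mKO muscle gained a call (adjusted p = 0.0450). Deviations of same-numbered samples from their group means correlated between -0.36 and 0.64. Between genotypes, replicate 3 deviated together in controls (0.636), unloading (0.445) and diabetes (0.218), while replicate 4 went apart in unloading (-0.36). There 3, 4 and 5 of 8 samples matched their own number best, in that order of conditions. Between control and treated samples of a genotype 1 or 2 of 8 did. Whether the numbers pair samples of the 2 genotypes stays open.

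Notch2, with 51 to 166 counts per library, had an SE of 0.24 between genotypes in controls. How much of this comes from depth was not tested. A call over all genes needs a change of several SEs, so changes in Notch2 well above 0.24 could have been missed.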

Other observations

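The direct comparison of diabetes with unloading was chosen after seeing the data, while the tests of other splits and the 3 tests of Fbxo32 were written down before their results were seen.

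Diabetes and unloading were set against each other within each genotype, which the planned comparisons left out. Ddit4, a stress-induced inhibitor of mTORC1, was at 128 ± 43.7 CPM (SD, n = 4) in diabetic and 9.63 ± 2.69 in unloaded WT muscle (log2 fold change 3.73, adjusted p = 5.5e-04 by edgeR), and at 120.5 ± 34.97 and 11.03 ± 7.47 in Notch2-mKO (3.45, adjusted p = 0.00104). Fabp3, which carries fatty acids in the cytosol, was at 656 ± 42.5 against 169 ± 35.5 CPM in WT and 689 ± 119 against 174 ± 21.2 in Notch2-mKO. Foxo1, a transcription factor of the fasting response, was higher by 2.06 in WT and 1.94 in Notch2-mKO, and Scd1 was lower in diabetes in WT (-2.63) and Notch2-mKO (-2.38). In Notch2-mKO the Scd1 values overlapped, at 8.52 to 47.3 CPM in diabetes and 29.3 to 239.9 in unloading. Unloading replicate 3 was highest there (239.9, others 29.3 to 104.4). Fatty acid oxidation genes were higher in diabetes in 18 of 29 cases in both genotypes (21 in WT and 26 in Notch2-mKO adjusted over the list alone; camera adjusted p = 3.3e-24 and 3.7e-32), the 1 list called in each with an estimated correlation too (adjusted p = 0.0462 and 0.0128). Glucocorticoid and FOXO responsive genes were higher in 6 of 20 cases in both genotypes (13 and 12 adjusted over the list alone; adjusted p = 1.1e-09 and 9.8e-13, and 0.196 and 0.0754 with an estimated correlation). Proteasome genes were lower in diabetes, 6 of 32 in WT and 5 in Notch2-mKO (21 and 20 adjusted over the list alone; adjusted p = 3.0e-12 and 4.3e-11, and 0.52 and 0.49 with an estimated correlation). These calls depend on single libraries. In WT 0 proteasome genes were called without WT unloading replicate 1, which stood apart for Psmb2 and Psmc3, 3 without unloading replicate 2 or diabetes replicate 1 or 3, and 2 without diabetes replicate 2 or 4. In Notch2-mKO 0 were called without unloading replicate 1 or diabetes replicates 1, 2 or 4, and 1 without unloading replicate 4 or diabetes replicate 3. Psmb7 was not called in WT with the trend removed (-0.39, adjusted p = 0.0865). In all, 302 genes were higher and 162 lower in WT and 254 and 146 in Notch2-mKO. The WT count of 464 fell to 309 and 300 without unloading replicates 1 and 2 and to 278 without diabetes replicate 2, and the Notch2-mKO count of 400 to 264, 195, 260 and 241 without diabetes replicates 1 to 4. Of these genes 170 were higher and 62 lower in both genotypes, where independent lists would share 5.88 and 1.81, and 0 were opposite, by edgeR.

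Myh3, the embryonic myosin gene, went in opposite directions in the treatments: it fell with unloading by 1.46 in WT and 1.69 in Notch2-mKO on the log2 scale and rose in diabetes by 1.81 and 1.51. Its change in diabetic WT muscle was 1.08 without diabetes replicate 3 (adjusted p = 0.0227). In Notch2-mKO its calls were lost in 3 of 8 fits with a library left out for unloading (adjusted p 0.0564 to 0.0613) and in 5 for diabetes (0.0619 to 0.105). In diabetes the pericyte gene Cspg4 fell in WT (-1.23) and Notch2-mKO (-0.97), while Rgs5, another pericyte gene, rose in WT (1.51; 1.01 with the trend removed).

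Fbxo32 varied widely within groups, and a hypothesis was that it may follow the glucocorticoid and FOXO responsive genes of the same library more than other genes do. Within groups, over 24 libraries, it correlated with the mean of the 20 genes of that list (Pearson r = 0.467, permutation p = 0.0255, adjusted p = 0.034 in a family of 4; Spearman rho = 0.532, permutation p = 0.0165; r = 0.668 without the 2 libraries farthest out). Trim63 correlated with it too (r = 0.644, permutation p = 3.6e-04, adjusted p = 0.00144; rho = 0.703, permutation p = 6.8e-04; r = 0.763 without the 2 farthest). A GC trend of the libraries is argued against, since r was 0.493 with the trend removed (permutation p = 0.014, adjusted p = 0.0278; rho = 0.552, permutation p = 0.0129; r = 0.695 without the 2 farthest). Library size had r = 0.309 with Fbxo32 (permutation p = 0.31; rho = 0.217, permutation p = 0.394; r = -0.0634 without the 2 farthest). Of 100 random lists matched on expression 74 correlated less with Fbxo32, and the highest reached 0.808, so the hypothesis is not favoured over a wider co-variation of the libraries.

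Other splits of the same libraries were counted for each comparison, refitting only the compared groups. For the treatments the real split called the most genes. It gave 4283 for unloading in WT with at most 0 in the 34 other splits, and 331 against 0 in Notch2-mKO. For diabetes it gave 3681 against 1 in WT and 1592 against 1 in Notch2-mKO. Between diabetes and unloading it gave 257 against 1 in WT and 332 against 1 in Notch2-mKO. Each was the 1 split of 35 with as many, the smallest share that 35 splits allow. Every other split mixes the 2 groups, so these counts cannot tell the treatment from a library trend that runs with it. Between genotypes chance cannot be excluded in controls, where the real split gave 1 gene, 3 of 35 splits gave as many and the highest gave 78, or in unloading (1 gene, 2 of 35 splits, highest 1). Between genotypes in diabetes and for the differences in response the real split gave 0 genes, which every split reaches (35 of 35, and 100 of 100 regroupings for each difference), so that these counts test nothing. The highest other values there were 4 for genotypes in diabetes, 188 for the unloading difference and 1433 for the diabetes difference. The splits with 78, 188 and 1433 genes set WT control replicates 1 and 3 with Notch2-mKO control replicates 2 and 3 against the other 4 controls, which points to a structure of the control libraries unrelated to genotype.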
